A study of Mus musculus with 8 samples.

How the data were processed

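Single-cell RNA sequencing was done on mouse bone marrow cells sorted as LSK (lineage-negative, Sca-1-positive, Kit-positive) or LK (lineage-negative, Kit-positive). There were 3 libraries of WT LSK cells, 3 of WT LK cells and 2 of LK cells from mice homozygous for W41, a partial loss-of-function allele of Kit. The deposited values are raw counts of UMIs (unique molecular identifiers) per gene and cell barcode, 1 table per library, made by the authors with Cell Ranger 1.3 on mm10 (GRCm38). Empty droplets had been removed before deposit: the barcode with the fewest UMIs had 1932. Of the 27998 genes in the tables, 27645 identifiers matched a symbol in the mouse annotation. Positions came from GENCODE vM21.

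Cells with fewer than 500 genes (45 barcodes) or a mitochondrial share above 10% (98 barcodes) were removed. The cells with the highest Scrublet scores were then removed as doublets, in the number expected from 0.8% per 1000 barcodes. This took 3733 barcodes and left 57246 of 61122. The threshold that Scrublet chose itself marked only 2 barcodes in the LSK libraries, against 3.05% in WT LK and 3.98% in W41 LK, so it was not used. Counts were scaled to 10000 per cell and logged. WT cells were clustered on 2000 variable genes (cell cycle, histone, mitochondrial, ribosomal and sex-linked genes left out), 50 principal components, 15 nearest neighbours and Leiden resolution 1. W41 cells were placed in the WT clusters by the majority of their 15 nearest WT cells. WT cells placed in the same way returned to their own cluster in 94.5% of cases, and in 50.5% when only the least shifted genes were used. The 94.5% came from the same neighbours that had defined the clusters, so it is high by construction. It is therefore no fair standard for the 50.5%. Neither share measures how well W41 cells were placed.

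A cluster took the name of a cell type when at least 3 of that type's listed markers passed a log2 fold of 1 over other cells with at least 20 CPM (counts scaled to library size). These naming thresholds were set after the data had been seen. The cluster with basophil and mast cell markers was clustered again on 20 principal components, also a choice made after the data had been seen. Clusters without a name kept their number and were tested beside the named classes, 16 in all.

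A library was the replicate. UMI counts were summed over the kept cells of a library and fitted with edgeR (quasi-likelihood F test, TMM scaling, filterByExpr, 3 groups in 1 fit). Genes within a class were fitted in the 5 LK libraries where each library had at least 20 cells of the class. Cells per class were fitted with edgeR with the total of kept cells as library size. An exact two-sided permutation test was run beside it; its smallest possible p is 0.2 for W41 against WT and 0.1 for LSK against LK. P-values were adjusted by Benjamini-Hochberg over genes, classes or lists, with a threshold of 0.05. All fold changes are log2, with edgeR's SE, and CPM values are TMM-scaled means with SD over libraries.

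For gene sets, 18 pathway lists and 14 cell type marker lists were tested with camera at a preset correlation of 0.01, camera with an estimated correlation, and fry. The sex-linked list was dropped because too few of its genes were measured, which left 31. The estimate of the correlation rests on few libraries. Fry asks whether a list moves on balance in 1 direction and does not compare it with other genes.

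The groups, tests, lists and most alternatives were fixed before the data were examined. Genes named for all cells were Kit and Ly6a, the 10 highest and 10 lowest log2 changes among genes past the threshold (at least 20 CPM in the higher group, no overlap between libraries), and up to 4 list members with the smallest p. Within a class they were Kit and the 5 highest and 5 lowest with 50 CPM. That rule did not say how CPM was scaled, and TMM-scaled CPM was chosen after the first result was seen. With plain CPM, 18 of the 20 W41 genes stayed (Snhg12 and Fos in place of Phlda3 and Zfp608), and 20 of 20 LSK genes. Other genes named are the sorting and gate genes fixed with the design, or list members that show what a list does. A few genes are not reported here.

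Alternatives were other scaling (RLE, library total), tests (DESeq2, glmTreat against a fold of 1.5, limma on shares), filters, depths, resolutions (0.5 and 2), classification and leaving out each library. Chosen after the data had been seen were other ways to split clusters 10, 13 and 17, the placing of W41 cells after thinning, after removing the expression shift shared by W41 classes or with the least shifted genes, clusters in place of classes, and a model with a term for each library. In simulated data that held 1.5-, 2- and 4-fold changes together, 100% of the 2-fold changes were recovered over all cells, 100% in the erythroid class and 58.2% in the stem class, where 16.4% of the 1.5-fold changes were recovered. Over all 3 sizes, 3.85% of calls were false for W41 and 6.54% for LSK. Each gene simulation changed only 67, 67 and 66 genes at the 3 sizes, of 14364 simulated over all cells. Far more genes were called in the data. The false shares therefore leave out errors that scaling makes when most genes change. The model with a term for each library, simulated for erythroid cells alone, recovered 97.0% of 2-fold and 35.8% of 1.5-fold changes. Of its calls over all 3 sizes, 12.99% were false. In 50 simulated sets of class counts all 2-fold changes were called, and 0.714% of unchanged classes.

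Software was Python 3.11.15, scanpy 1.11.5 (with its Scrublet), anndata 0.12.19, leidenalg 0.10.2, igraph 0.11.9, scikit-learn 1.9.0, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3, matplotlib 3.10.9, R 4.3.3, edgeR 4.0.16, limma 3.58.1 and DESeq2 1.42.0.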

Results

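Single-cell transcriptomes were collected from bone marrow progenitors in 3 groups: WT LSK (n = 3 libraries, replicates 1 to 3), WT LK (n = 3, replicates 4 to 6) and W41 LK (n = 2, replicates 39 and 40). The LSK libraries held 67850194, 60213336 and 53831307 UMIs, the WT LK libraries 81066308, 85615271 and 81310491, and the W41 libraries 137605307 and 126055620. Kept cells numbered 21863 in WT LSK, 21588 in WT LK and 13795 in W41 LK, with medians of 6360, 8231 and 14590 UMIs per cell (6576, 8497 and 15190 over all deposited barcodes). Ribosomal protein genes took 28.8% of UMIs in both WT groups and 36.9% in W41. The labels state that the WT libraries came from a pool of 6 mice and give no number for W41. The p-values therefore measure only the spread between these libraries, which may be technical. Each fit estimates the spread of a gene or class jointly over its groups, mostly from WT libraries. P-values and SEs for W41 thus assume that W41 libraries vary like WT libraries. Genotype goes with sample number, depth and ribosomal share, so W41 and library batch cannot be told apart.

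The comparison of W41 LK with WT LK asks what reduced Kit signalling changes in Kit-positive progenitors. The LK gate selects on the product of the mutated gene. Whether it took the same cells from both genotypes was not tested. Kit itself (ENSMUSG00000005672, chromosome 5, 75574916 to 75656722), the receptor for stem cell factor, fell from 115 ± 1.76 CPM (SD, n = 3) to 42.8 ± 1.25 CPM (n = 2), a log2 change of -1.43 (SE 0.03, adjusted p = 1.43e-13). Btg2 (ENSMUSG00000020423, chromosome 1, 134075170 to 134079120), an antiproliferative immediate early gene, fell from 25.7 ± 0.975 to 3.66 ± 0.326 CPM (-2.81, SE 0.06). Angpt1 (ENSMUSG00000022309, chromosome 15, 42424723 to 42676977), the ligand of Tie2 that haematopoietic stem cells make, fell from 99.4 ± 2.94 to 25.5 ± 0.825 CPM (-1.96, SE 0.03). Ctse (ENSMUSG00000004552, chromosome 1, 131638306 to 131675505), an aspartic protease of erythroid and other cells, rose from 81.9 ± 4.34 to 329 ± 2.10 CPM (2.00, SE 0.05).

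Among the genes with the lowest changes were Rgs1 (-1.94), which damps signalling by chemokine receptors, Slc18a2 (-1.84), the vesicular monoamine transporter of mast cells and basophils, Ccng2 (-1.78), a cyclin of quiescent cells, and Irgm1 (-1.75), an interferon-induced GTPase. Erbin, Pcmtd2, Zfp608 and the Y-annotated model Gm47283 lay between -1.67 and -1.76. The highest changes were in the adult globin genes Hbb-bs (2.19) and Hbb-bt (1.81), the antisense transcript Tnfsf13os (2.11), the histone gene Hist1h2ap (2.08), Rfesd (2.00), the p53-induced Phlda3 (1.95), the lincRNA AY036118 (1.81) and the ribosomal protein genes Rps12 (1.97) and Rpl30 (1.80). Rps12 and Rpl30 have near-identical pseudogene copies, so their counts are uncertain. Hbb-bs stood at 393 CPM in replicate 40 and 86.2 CPM in replicate 39; without replicate 40 its change was 0.72 and that of Hbb-bt 0.90, without replicate 39 that of Hbb-bs was 2.91, and with all barcodes it was -0.0762 and Hbb-bt missed the threshold.

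Over all genes, edgeR called 10597 of 14364 tested, 5261 higher and 5336 lower in W41. At least a 2-fold change was seen for 520 of the higher and 1108 of the lower genes. W41 libraries gave more of their UMIs to few genes (43.9 and 43.0% to the top 100, 35.8 to 36.3% in WT LK), and scaling set the balance of directions. With the library total in place of TMM the median of all genes moved from -0.0276 to -0.58, with 1523 higher and 10241 lower.

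ERK feedback, immediate early and stem cell genes were lower in W41. This and the following list changes are for sums over all cells, whose mix of classes also differed. Of the 14 measured ERK feedback genes, which restrain and report signalling by receptor kinases, 12 fell and 1 rose (adjusted over the list alone, 12 and 1), with Spry2 at -1.93, Dusp6 at -1.71, Ccnd1 at -1.36 and Spred1 at -1.21. Of 15 immediate early genes, 13 fell and none rose (adjusted over the list alone, 13), among them Egr1 (-2.51), Fos (-1.69) and Jun (-1.36). Of 10 stem cell markers, 6 fell and 2 rose (adjusted over the list alone, 6 and 2), with the transcription factors Mycn at -1.96, Hlf at -1.51 and Mecom at -1.27. Of 11 replication-dependent histones 7 fell and 1 rose (adjusted over the list alone, 7 and 1), among them Hist2h2ac (-1.40) and Hist1h1e (-1.17). Of 11 megakaryocyte markers 6 fell and 3 rose (adjusted over the list alone, 7 and 3), with Plek, a platelet kinase substrate, at -1.60 and the integrin Itga2b at -1.29, whereas platelet factor Pf4 rose (0.43; -0.13 with the library total); with the library total all 11 fell.

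Camera at the preset correlation placed these lists lower than other genes. The adjusted p was 0.00416 for ERK feedback (adjusted p = 0.377 with an estimated correlation) and 1.25e-05 for immediate early genes (adjusted p = 0.377 with an estimated correlation). It was 0.00742 for stem markers (adjusted p = 0.377 with an estimated correlation), 0.0266 for histones (adjusted p = 0.714 with an estimated correlation) and 0.0282 for megakaryocyte markers (adjusted p = 0.518 with an estimated correlation).

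Erythroid, haem synthesis and neutrophil genes were higher in W41. Of 16 erythroid markers 14 rose and none fell (adjusted over the list alone, 14), including the biliverdin reductase Blvrb (1.09), Cldn13 (1.31) and the master regulators Klf1 (0.81) and Gata1 (0.57); with the library total 7 rose, 4 fell and Gata1 lost its call (0.0101). Of 12 haem synthesis genes 10 rose (adjusted over the list alone, 10), among them Alad (0.98) and Urod (0.75); with the library total 6 rose and 5 fell. Of 14 neutrophil markers 9 rose (adjusted over the list alone, 9), with the granule proteases Ctsg at 1.01 and Prtn3 at 0.62; with the library total 5 rose, 1 fell and Prtn3 lost its call (0.0597). The adjusted p was 0.00742 for erythroid markers (adjusted p = 0.518 with an estimated correlation), 0.00416 for haem synthesis (adjusted p = 0.377 with an estimated correlation) and 0.0251 for neutrophil markers (adjusted p = 0.732 with an estimated correlation).

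Chaperones and mitotic genes also rose under TMM, and their balance turned with the library total. Of 11 heat shock genes 8 rose and 2 fell (adjusted over the list alone, 8 and 2), with the mitochondrial chaperonin Hspe1 at 1.61, Hsp90aa1 at 1.25 and the inducible Hspa1a at -2.46; with the library total 4 rose and 4 fell. Of 13 unfolded protein response genes 11 rose and 2 fell (adjusted over the list alone, 11 and 2), with Atf4 at 1.47, and with the library total 3 rose and 7 fell. Of 25 genes of G2 and M phase 17 rose and 4 fell (adjusted over the list alone, 17 and 4), with Ube2c at 1.46 and Cdk1 at 0.88, and with the library total 10 rose and 13 fell. Of 14 glycolysis genes 9 rose and 2 fell (adjusted over the list alone, 9 and 2), with Tpi1 at 0.99, and with the library total 2 rose and 9 fell. The adjusted p was 0.0076 for heat shock (adjusted p = 0.518 with an estimated correlation), 0.00816 for the unfolded protein response (adjusted p = 0.518 with an estimated correlation), 0.00215 for G2 and M phase (adjusted p = 0.718 with an estimated correlation) and 0.0383 for glycolysis (adjusted p = 0.714 with an estimated correlation).

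Mast cell markers were not called as a list (adjusted p = 0.409), though 3 of 4 fell (adjusted over the list alone, 3): carboxypeptidase Cpa3 was at -1.15, granzyme Gzmb at -1.08 and chymase Cma1 at -1.89, and Hdc did not pass (0.0116). The Cma1 call was lost without WT LK replicate 5 (-0.93), without W41 replicate 40 (-1.57), with DESeq2 (-1.84) and with doublets kept (-0.22). STAT5 target genes were not called either (adjusted p = 0.578), with 6 higher and 3 lower of 10 (adjusted over the list alone, 6 and 3), and 2 and 5 with the library total; nor were macrophage markers (adjusted p = 0.883). Among the STAT5 target genes the feedback inhibitor Socs2 rose (1.63). Gata2, which drives mast cells and early progenitors, fell (-1.27), whereas Gfi1b, a transcriptional repressor that acts within erythroid and platelet lineages, rose (1.08). In all, 12 of 31 lists were called at the preset correlation and 0 with camera's estimated correlation, where 4 had an unadjusted p under 0.05; fry called 24.

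Cells were spread over the lineages differently in W41 LK, where the gate on Kit may set part of the shares. Erythroid cells made up 49.7 ± 0.390% (SD, n = 2) of W41 cells and 41.3 ± 0.377% (n = 3) of WT cells (log2 ratio 0.27, SE 0.03, adjusted p = 3.24e-11). Neutrophil-lineage cells (clusters 7 and 10) rose from 19.0 ± 0.280% to 24.2 ± 0.252% (0.35, adjusted p = 5.50e-11). Of these, cluster 10 rose (0.56) and cluster 7 did not pass the threshold (0.10, adjusted p = 0.129). Stem cells fell from 2.14 ± 0.101% to 1.06 ± 0.0883% (-1.02, adjusted p = 1.05e-08), lymphoid progenitors from 4.02 ± 0.211% to 1.88 ± 0.288% (-1.11, adjusted p = 1.75e-12) and megakaryocyte-lineage cells from 12.9 ± 0.286% to 8.40 ± 0.498% (-0.62, adjusted p = 2.48e-13). In each of these classes both W41 libraries lay beyond all 3 WT libraries, with an exact permutation p of 0.2, the smallest that 2 against 3 libraries allow.

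Mast cells numbered 9, 17 and 7 in the WT LK libraries and 0 and 1 in W41 replicates 39 and 40 (-4.10, adjusted p = 0.000104). The log2 ratio was -3.16 without replicate 39. Without replicate 40 the W41 group held 0 mast cells, so the -6.49 of that fit is not a measured size. The mast class came from splitting a cluster of basophils and mast cells after the data had been seen. With that split at resolution 0.5 no mast class was named. The 0 of 7353 cells in replicate 39 allows a share of up to 0.0408% (3 counts of the total; the exact Clopper-Pearson limit is 0.0502%), and the 1 of 6442 in replicate 40 is 0.0155% (95% exact Clopper-Pearson interval 0.000393 to 0.0865%). Such intervals and limits cover counting error only. Basophils fell from 0.686 ± 0.151% to 0.462 ± 0.115% (-0.58, adjusted p = 0.0313), a call that was lost without WT LK replicate 5 (-0.61, adjusted p = 0.0683), WT LK replicate 6 (-0.41, 0.225) or W41 replicate 39 (-0.33, 0.299). B cells missed the threshold (-1.18, adjusted p = 0.0501), with an exact permutation p of 0.4. They numbered 16, 11 and 16 in the WT LK libraries and 1 and 11 in W41 replicates 39 and 40. The share in replicate 40 (0.171%) lay within the WT LK range (0.148 to 0.226%), so the fall rests on replicate 39. Without replicate 40 the log2 ratio was -3.71, from 1 W41 cell. B cells passed the threshold with W41 cells thinned before placing (-1.44, 0.00450), with the shared expression shift removed (-1.18, 0.0177) and with both steps (-1.18, 0.0190). They also passed with at least 1000 genes per cell (-1.10, 0.0372) and with limma on shares (-1.12, 0.0141). T and NK cells (-0.10, 0.796) and dendritic cells (0.17, 0.713) did not pass. T and NK cells passed in opposite directions with all libraries clustered together (1.81, 0.0399) and by marker scores (-0.29, 0.00221).

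Some class values hung on how cells were assigned. When all 8 libraries were clustered together, the log2 ratios of stem, lymphoid and basophil cells were -7.22, -5.74 and -9.04. In the main fit they were -1.02, -1.11 and -0.58. W41 cells took part in forming the joint clusters, so they could fall outside the clusters that were named. Whether they did was not tested, so the joint values are not taken as sizes of a loss of cells. At resolution 2, stem cells stood at -1.75 and lymphoid cells at -0.44; with doublets kept, lymphoid cells stood at -0.15. Stem cells stood at -2.59 when W41 cells were placed with the least shifted genes, a placing that returned 24.6% of WT cells of the stem cluster to it. All variable genes returned 84.0%, but by the same neighbours that had defined the clusters. These shares therefore do not tell which placing is better. With TMM over classes, which assumes that most classes did not change, stem (-0.46), megakaryocyte (-0.0547) and basophil (-0.0246) calls were lost. Shares are parts of a whole, so a rise of some classes lowers the shares of the others. The falls in share of these classes therefore do not tell fewer such cells from more cells of other classes. The basophil call was also lost at resolutions 0.5 (-0.45) and 2 (-0.51), with at least 1000 genes per cell (-0.17), with doublets kept (-0.46) and with only both LK groups in the fit (-0.58). Mast cells stood at -1.64 when cells were classed by marker scores, with 7.17e-18 as adjusted p. With cluster 10 split again, neutrophils stood at 0.23 and the unnamed rest of cluster 10 at 0.60. Monocytes, which the main neutrophil class had held, missed the threshold (-0.34, adjusted p = 0.0508).

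**Figure D1:**
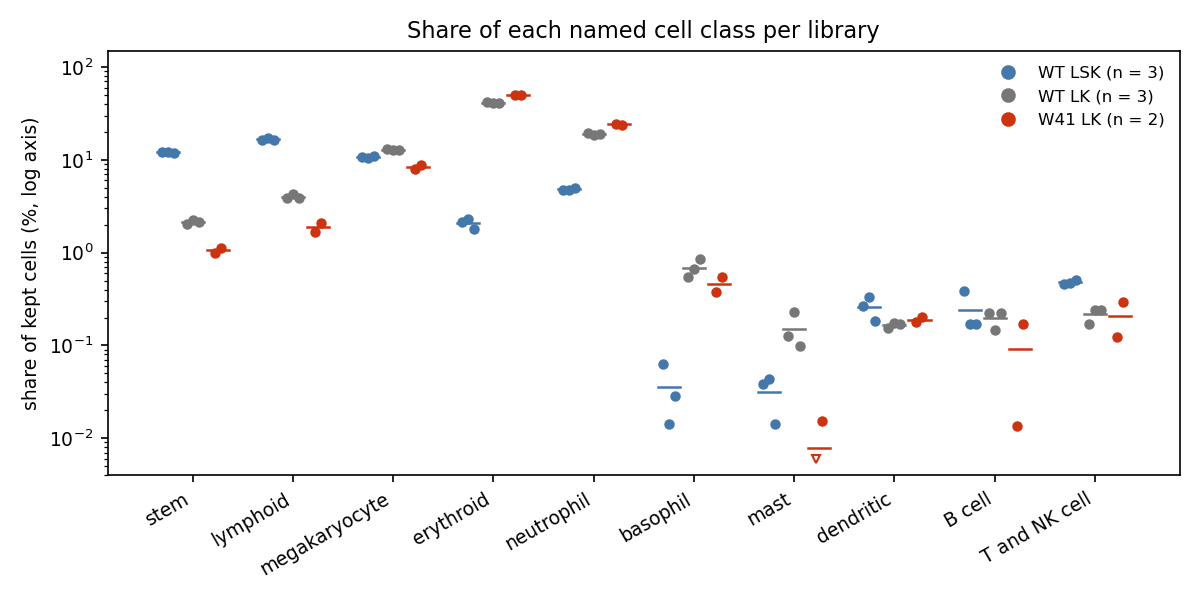
Share of kept cells in each named class (percent, log axis) in WT LSK, WT LK and W41 LK; dots are libraries, bars are group means and the open triangle marks the library with 0 mast cells. Erythroid cells are at 49.7% in W41 and 41.3% in WT LK, and stem cells at 1.06 and 2.14%.

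Clusters of the erythroid lineage moved apart in W41, in a fit with clusters in place of classes. Cluster 5, with low counts per cell and Klf1, Gata1, Car1 and Aqp1 as markers, fell from 15.03 ± 0.278% to 3.86 ± 0.760% of cells (-1.98, SE 0.07, adjusted p = 2.29e-46). Cluster 8, with the red cell genes Rhd, Ermap, Cldn13 and Sphk1, rose from 13.7 ± 0.495% to 33.3 ± 1.45% (1.29, SE 0.04, adjusted p = 2.85e-48). Cluster 9 stood at 12.5 ± 0.224% in WT and 12.4 ± 0.198% in W41, and the globin-rich cluster 18 at 0.111 ± 0.0162% in WT and 0.128 ± 0.104% in W41, neither past the threshold. When the expression shift shared by other W41 classes was removed before placing, cluster 5 stood at -1.42 and cluster 8 at 1.11; with W41 cells also thinned to the median depth of WT LK cells, cluster 5 was at -1.39.

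**Figure D2:**
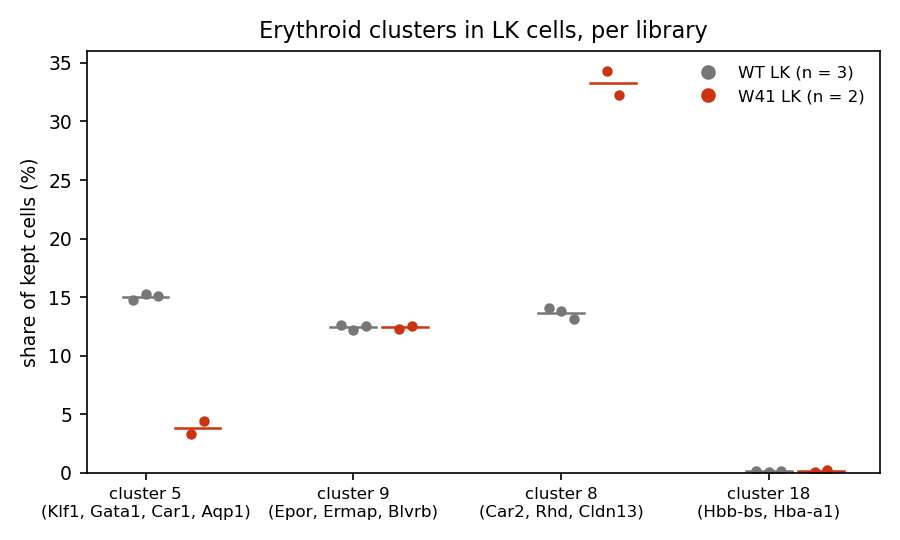
Share of kept cells (percent) in erythroid clusters 5, 9, 8 and 18 in WT LK and W41 LK; dots are libraries and bars are group means. Cluster 5 is at 15.03% in WT and 3.86% in W41, and cluster 8 at 13.7 and 33.3%.

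Among clusters that no marker list named, cluster 0, rich in Hlf and Cd34, fell from 5.27 ± 0.196% to 1.52 ± 0.531% (-1.82, adjusted p = 1.14e-18). It stood at -0.76 with the shift removed and at -0.48 with the least shifted genes, which returned only 48.2% of its WT cells. Cluster 14, marked by the interferon-induced Ifit1, Iigp1, Isg15 and Rsad2, fell from 0.288 ± 0.0641% to 0.0282 ± 0.0179% (-3.23, adjusted p = 2.39e-06). It held 24, 16 and 22 cells in WT LK libraries and 3 and 1 in W41. Placing with all variable genes returned 68.8% of its WT cells, by the same neighbours that had defined the cluster. The rest of cluster 13 (-0.86) and cluster 12 (-0.44) were also lower, and clusters 2 (0.09) and 3 (0.10) did not pass the threshold.

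Kit was lower in W41 in each of the 6 named classes and 5 numbered clusters with enough cells. Its log2 change was -1.48 (SE 0.17; 213 ± 11.2 to 76.0 ± 6.44 CPM) in stem cells, -1.61 (SE 0.07) in megakaryocyte-lineage, -1.47 (SE 0.05) in neutrophil-lineage and -1.45 (SE 0.04) in erythroid cells. In lymphoid cells it was -1.21 (SE 0.16; -0.80 without replicate 40 and -1.63 without replicate 39), and in basophils -2.15 (SE 0.36; -3.22 without replicate 40). In the numbered clusters it ran from -1.57 (cluster 0) to -1.11 (cluster 3). The cytokine signalling inhibitor Socs2 (2.74) and the stress-induced Nupr1 (2.83) rose in stem cells, where the cation transporter Slc22a3 (-2.01) fell. Lymphoid cells had less Hlf (-1.76) and Btg2 (-2.45), and more of the cytochrome oxidase subunit Cox6a2 (2.51). In megakaryocyte-lineage cells the matrix protease inhibitor Timp3 (2.04) rose and Btg2 (-2.99) fell. Neutrophil-lineage cells, with a larger part in cluster 10 in W41 than in WT, lost Angpt1 (-1.53) and the heterochromatin protein gene Cbx3 (-1.71). In basophils the IgE receptor chain Fcer1a rose (2.30; 3.43 without WT LK replicate 6). Erythroid cells, which were mostly of clusters 5, 8 and 9 in WT and of cluster 8 in W41, had less Gata2 (-1.67), Sox4 (-1.60) and Jun (-1.62) and more of the lipid carrier Fabp5 (2.03).

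**Figure D3:**
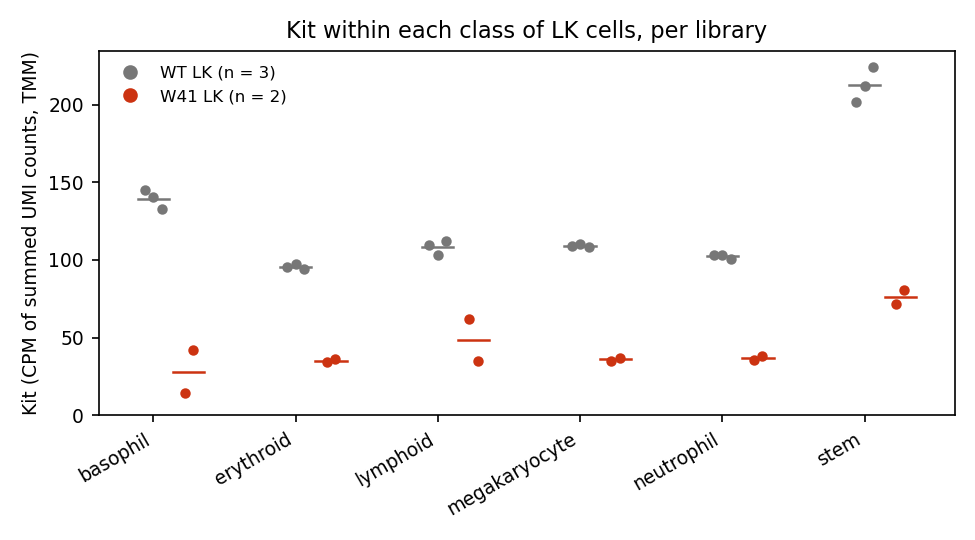
Kit (TMM-scaled CPM of counts summed per library and class) in WT LK and W41 LK for each named class tested; dots are libraries and bars are group means. Stem cells are at 213 CPM in WT and 76.0 in W41, and the W41 libraries lie below the WT libraries in every class drawn.

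edgeR called 9115 of 12054 genes in erythroid cells, 7350 of 11602 in the neutrophil lineage, 6159 of 11087 in the megakaryocyte lineage, 2977 of 9425 in lymphoid cells, 1703 of 7867 in stem cells and 472 of 3820 in basophils. Without replicate 40 the counts were 252 in basophils, 1882 in lymphoid cells and 1087 in stem cells, and without replicate 39 they were 1024 in stem cells. DESeq2 called 205 in basophils, 1438 in lymphoid cells and 674 in stem cells. Of the 3737 genes tested in all 6 named classes, 191 were called higher in every class and 121 lower in every class.

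The comparison of LSK with LK in WT mice asks how the Sca-1-positive fraction, which holds stem cells and multipotent progenitors, differs from all Kit-positive progenitors. Ly6a (ENSMUSG00000075602, chromosome 15, 74994877 to 74998031), which encodes Sca-1, was at 44.8 ± 0.642 CPM (SD, n = 3) in LSK and 7.63 ± 0.143 CPM (n = 3) in LK (2.55, SE 0.03, adjusted p = 2.22e-16). Kit was higher by 0.22 (SE 0.02; 134 ± 1.43 and 115 ± 1.76 CPM). The stem cell transcription factors Hlf (2.28, SE 0.02; 191 ± 1.71 and 39.3 ± 0.445 CPM) and Mecom (2.23, SE 0.05) were higher. So were Dntt (2.28), the polymerase of early lymphoid progenitors, the cytokine gene Ltb (2.30), the homeobox gene Nkx2-3 (2.38) and Vldlr (2.22). Sphk1 (ENSMUSG00000061878, chromosome 11, 116530925 to 116536674), a sphingosine kinase of red cell precursors, was lowest (-5.51, SE 0.06; 1.86 ± 0.193 and 84.3 ± 0.608 CPM). Pyruvate kinase Pklr (-5.46), the red cell skeleton gene Add2 (-5.45), the blood group gene Rhd (-5.43) and Ermap (-5.12) were also lower.

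edgeR called 11417 of 14364 genes, 5845 higher and 5572 lower in LSK, of which 1957 and 791 changed at least 2-fold. With the library total the median of all genes moved from 0.0281 to 0.22. Erythroid programmes were lower: 12 of 16 erythroid markers fell and 1 rose (adjusted over the list alone, 12 and 1), with Klf1 at -4.25 and Gata1 at -2.60. Of 12 haem synthesis genes 10 fell and 1 rose (adjusted over the list alone, 10 and 1), with the transferrin receptor Tfrc at -2.68 and Cpox at -2.64. Of 12 erythroid and mast cell regulators 7 fell and 5 rose (adjusted over the list alone, 7 and 5), among them Gfi1b (-1.49) and the stem and erythroid factor Lmo2 (0.69). Stem markers rose in 8 of 10 and fell in 2 (adjusted over the list alone, 8 and 2), with the protein C receptor Procr at 2.39. All 10 lymphoid markers rose (adjusted over the list alone, 10), among them the cytokine receptor Flt3 (1.85), the chromatin organiser Satb1 (1.50) and Notch1 (1.44). The adjusted p was 6.32e-47 for erythroid markers (adjusted p = 0.0173 with an estimated correlation) and 1.42e-15 for haem synthesis (adjusted p = 0.0213 with an estimated correlation). It was 0.000119 for the regulators (adjusted p = 0.0450 with an estimated correlation), 1.32e-07 for stem markers (adjusted p = 0.0213 with an estimated correlation) and 4.73e-08 for lymphoid markers (adjusted p = 0.0283 with an estimated correlation).

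Proliferation genes were lower and interferon and cytokine target genes higher in LSK. Counts were summed over all cells of a library, and no difference between LSK and LK was tested within a class. These changes were therefore not told apart from the different mix of cells. All 25 S phase genes fell (adjusted over the list alone, 25), with cyclin Ccne1 at -2.94 and the licensing factor Cdc6 at -1.15; with the library total 19 fell and 2 rose. Of 25 genes of G2 and M phase 23 fell and 1 rose (adjusted over the list alone, 23 and 1), with Cenpa at -1.30. All 24 interferon response genes rose (adjusted over the list alone, 24), with Ifi44 at 1.87 and Oasl2 at 1.62. Of 10 STAT5 target genes 8 rose and 1 fell (adjusted over the list alone, 8 and 1), with Socs3 at 1.83 and the survival kinase Pim2 at 1.56. Of 11 heat shock genes 10 fell and 1 rose (adjusted over the list alone, 10 and 1), with the chaperonin Hspd1 at -1.02. All 12 MHC class I genes rose (adjusted over the list alone, 12), with H2-K1 at 0.56, and 9 of 10 dendritic markers rose (adjusted over the list alone, 9), with Tcf4 at 0.78. All 4 mast markers fell (adjusted over the list alone, 4), with histidine decarboxylase Hdc at -2.91. Of 14 neutrophil markers 5 fell and 2 rose (adjusted over the list alone, 5 and 2), with the elastase Elane at -3.94 and Cebpe, a factor of granule formation, at -3.39.

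None of these calls held when the correlation was estimated. The adjusted p was 2.49e-08 for S phase (adjusted p = 0.0970 with an estimated correlation), 1.25e-05 for G2 and M phase (adjusted p = 0.522 with an estimated correlation) and 5.23e-06 for interferon (adjusted p = 0.399 with an estimated correlation). It was 0.000697 for STAT5 targets (adjusted p = 0.118 with an estimated correlation), 3.09e-05 for heat shock (adjusted p = 0.201 with an estimated correlation) and 0.0314 for MHC class I (adjusted p = 0.548 with an estimated correlation). It was 0.0117 for dendritic markers (adjusted p = 0.125 with an estimated correlation), 0.0117 for mast markers (adjusted p = 0.287 with an estimated correlation) and 0.00233 for neutrophil markers (adjusted p = 0.548 with an estimated correlation). ERK feedback genes missed the threshold (adjusted p = 0.0552) with 11 of 14 higher, 2 lower (adjusted over the list alone, 11 and 2) and Dusp5 at 1.68. In all, 14 of 31 lists were called at the preset correlation and 5 with the estimated one. Other splits of the 6 WT libraries gave 8 to 17 lists at the preset correlation. Those splits mix LSK and LK libraries in both groups, so they give no level of calls by chance.

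The LSK gate selects on Sca-1 and so sets part of the shares of cells. Stem cells made up 12.04 ± 0.240% of LSK and 2.14 ± 0.101% of LK cells (2.49, SE 0.07, adjusted p = 9.52e-35). Lymphoid progenitors were at 16.6 ± 0.455% and 4.02 ± 0.211% (2.05). Erythroid cells were at 2.08 ± 0.280% and 41.3 ± 0.377% (-4.31), neutrophil-lineage cells at 4.82 ± 0.143% and 19.0 ± 0.280% (-1.98), basophils at 0.0355 ± 0.0254% and 0.686 ± 0.151% (-4.16) and mast cells at 0.0318 ± 0.0154% and 0.152 ± 0.0687% (-2.20). Megakaryocyte-lineage cells differed least among the called classes (-0.26; 0.0228 at resolution 2 and -0.0073 by marker scores, neither called). T and NK cells were higher (1.14; -0.15 by marker scores, 2.33 at resolution 2, and 0.60 and not called with TMM over classes), as was cluster 14 with its interferon-induced genes (1.78; 0.994 ± 0.0888% and 0.288 ± 0.0641%). By marker scores, basophils stood at -0.65 and mast cells at -1.29; neutrophil-lineage cells stood at -3.62 at resolution 0.5, -3.55 at resolution 2, -3.26 with all libraries clustered together, -3.68 with at least 1000 genes per cell and -3.63 with doublets kept, but at -1.37 by marker scores and with clusters 10 and 17 split again, and lymphoid cells at 1.06 with doublets kept. In total 8 of 10 named classes were called, each with an exact permutation p of 0.1, the smallest that 3 against 3 libraries allow. Dendritic cells missed the threshold (0.64, adjusted p = 0.0636), but passed it without LSK replicate 3 (0.82, 0.0130), at resolution 2 (0.64, 0.0471), with doublets kept (0.62, 0.0492), with only both WT groups in the fit (0.64, 0.0357) and by marker scores (1.59, 4.52e-26). B cells did not pass (0.31, 0.410), but did by marker scores (0.77, 1.16e-05).

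Among gate genes, Cd34 stood at 451 ± 8.03 CPM in LSK, 168 ± 4.92 in WT LK and 130 ± 1.24 in W41 LK, and Flt3 at 122 ± 3.27, 33.8 ± 1.43 and 12.8 ± 1.60. Fcgr3, the Fc receptor of granulocyte and macrophage progenitors, stood at 2.21 ± 0.339, 19.3 ± 1.74 and 28.0 ± 4.41 CPM; its rise in W41 (0.53) turned to -0.0190 with the library total. Fcgr2b, an inhibitory Fc receptor, rose in W41 (0.32; -0.23 with the library total), Slamf1 fell (-0.44) and Cd48 did not pass the threshold (-0.0213). Ly6a was higher in W41 than in WT LK (0.45, SE 0.04; 10.4 ± 0.114 and 7.63 ± 0.143 CPM), but lower with the library total (-0.11). With each cell thinned to 3000 UMIs, a Ly6a UMI was seen in 15.1% of LSK, 3.31% of WT LK and 3.32% of W41 LK cells. In the late erythroid cluster 8, taken as background, it was seen in 2.08, 0.102 and 0.109%. Cluster 8 held 49 cells in LSK, 2952 in WT LK and 4603 in W41 LK. Its LSK cells were sorted for Sca-1, and 22.4% had a Ly6a UMI before thinning, so they are not a clean background. Median depths before thinning were 6360, 8231 and 14590 UMIs over all cells. In cluster 8 they were 23372, 22846 and 27919 UMIs.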

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

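All tests of explanations in this part were chosen after the results they measure had been seen.

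The effect of W41 was called different between classes of cells for a minority of the genes tested. A model with a term for each library compared each class with the mean of the other 5. It was simulated for erythroid cells alone, where 12.99% of calls were false and 35.8% of 1.5-fold changes were recovered. Its power in the other classes was not measured, so the counts that follow do not rank the classes. Of 12171 genes tested, the W41 effect differed for 2570 in erythroid cells, 578 in the neutrophil lineage and 182 in basophils. It differed for 161 genes in lymphoid cells, 115 in the megakaryocyte lineage and 95 in stem cells. Kit was not among them in any of the 6 classes (adjusted p from 0.331 to 1).

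In erythroid cells the log2 effect was lower than in other classes for Ctse (-2.97), Sox4 (-1.31), Gata2 (-1.21) and Jun (-0.72), and higher for Hbb-bs (2.98), Fabp5 (0.95), Gm47283 (0.81), Snhg12 (0.70) and Hist1h2ap (0.37). Erythroid cells were mostly of clusters 5, 8 and 9 in WT and of cluster 8 in W41, so these differences hold a change of stage. The Hbb-bs value rests mostly on 1 library: in erythroid cells it stood at 110 and 517 CPM in the W41 libraries, and its change of 2.16 there was 0.65 without replicate 40. In basophils the effect was higher for Ctse (1.60) and Tpt1 (0.31) and lower for Hells (-2.19) and Rps12 (-0.18). In lymphoid cells the effect was higher for Hist1h2ap (0.71) and Rps12 (0.12). In the neutrophil lineage it was higher for Ctse (0.93) and lower for Rpgrip1 (-0.90), Cbx3 (-0.45), Rps12 (-0.20) and Tpt1 (-0.10). The same genes also differed in classes where the naming rule had not picked them: Tpt1 in erythroid cells (-0.27) and the megakaryocyte lineage (-0.15), Rps12 (0.20) and Jun (1.04) in stem cells, Hist1h2ap in basophils (-1.45), Cbx3 in erythroid cells (0.55), Rpgrip1 in erythroid (-0.37), megakaryocyte (-0.54) and lymphoid cells (0.78), Hells in erythroid (0.97), lymphoid (0.78) and megakaryocyte cells (0.58), and Sox4 in lymphoid cells (0.31) and the neutrophil lineage (0.16). Rps12 and Tpt1 have near-identical pseudogene copies, so their counts are uncertain.

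Kit mRNA was lower in W41. With summed counts thinned to the shallowest library the log2 change was -1.46, but random thinning keeps each gene's expected share of UMIs, so this decides nothing about depth, which stays open. Among the named classes the change closest to 0 was -1.21, in lymphoid cells (-0.80 without W41 replicate 40), and among the numbered clusters it was -1.11, in cluster 3; each lay below 0 by more than 2 SE, which argues against a change in the mix of classes as the whole cause. The W41 genotype may lower Kit mRNA, but 0 W41 libraries had a sample number among those of the WT libraries, so library batch and genotype cannot be told apart. A sequence difference between the strains at the read end of Kit was not tested and stays open.

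W41 libraries had fewer erythroid cells in cluster 5 and more in cluster 8. With 1 share of UMIs kept in all W41 cells, so that their median depth matched that of WT LK cells, cluster 5 stood at -2.05 and cluster 8 at 1.29, which argues against the higher median depth as the cause; depth was not matched cell by cell or within classes. With the expression shift shared by the non-erythroid W41 classes removed, the values were -1.42 and 1.11, and with both steps -1.39 and 1.03, which argues against that shift as the whole cause, though it may account for part of the fall in cluster 5. Faster passage through early erythroid stages in W41 is a candidate explanation that these data do not test. The fall of cluster 5 from 15.03 to 3.86% argues against a block that holds cells in that cluster. A block before cluster 5 was not tested. Library batch stays open, with 0 W41 libraries among the WT sample numbers. Selection of cells by the gate on Kit was not tested.

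Ctse was higher in W41 outside the erythroid class, by 4.02 in the megakaryocyte lineage, 3.97 in lymphoid cells, 4.11 in stem cells, 4.71 in the neutrophil lineage and 5.19 in basophils. If RNA of erythroid cells, free or in doublets, were the source, it would have to make up 38.1 to 132% of erythroid levels in these classes and bring 13 abundant erythroid markers with it. The median marker rose by at most 3.86% of what that share needs and the highest single marker by 8.95%, against a bound of 50% set for this source, which argues against it. A strain difference at Ctse, which was not tested, could give such a rise. Library batch stays open here as well, with 0 W41 libraries among the WT sample numbers.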

How the results depend on the processing

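Clusters in place of classes, a term for each library and other placings of W41 cells were chosen after the data had been seen. Of 1775 values of single genes under other settings, 1739 kept direction and side of the threshold, as did 589 of 600 for genes within classes and 333 of 368 for classes. For lists 148 of 202 did, while 30 lost their call, mostly with an estimated correlation, 23 gained one, all with fry, and 1 reversed. With the basophil and mast cluster split at resolution 0.5 no mast class was named, so that class has no value there. The count of genes ran from 9549 to 11764 in W41 and from 10491 to 11585 in LSK apart from a test against a fold of 1.5, which called 3186 and 3808 since it asks for larger changes. Leaving out 1 library gave 10020 to 10232 genes in W41, 10818 to 10990 in LSK and 6 to 8 W41 classes; where 1 W41 library was left, it is assumed to vary like the other groups. TMM over classes called 4 W41 classes, and marker scores 13 LSK classes, having more classes by construction. Within classes, 27776 calls became 60282 with clusters in place of classes (more units by construction) and 3701 with a term for each library (a different question). Camera with an estimated correlation called 0 lists in W41 (4 with an unadjusted p under 0.05) and 5 in LSK; fry, which asks another question, called 24 and 25. Reversed by the library total, which moves the median of all W41 genes to -0.58, were Ly6a (-0.11), Pf4 (-0.13), Hdc (-0.54), Fcgr3 (-0.0190) and Fcgr2b (-0.23). For the other reversals the cause was not tested: in W41, Hbb-bs with all barcodes (-0.0762), Cd48 with RLE (0.0258) and DESeq2 (0.0280), macrophage markers with fry (adjusted p = 0.980), T and NK cells at resolution 2 (1.81), with joint clustering (1.81) and with TMM (0.46), and dendritic cells by marker scores (-0.16); in LSK, B cells with TMM (-0.27), T and NK cells by marker scores (-0.15) and megakaryocyte cells at resolution 2 (0.0228). Leaving out 1 library moved Hdc between -0.0656 (without WT LK replicate 4) and 0.0615, W41 T and NK cells between -0.82 and 0.43 (without replicate 39) and LSK B cells between -0.22 (without LSK replicate 1) and 0.50. DESeq2 gave no adjusted p for Kit and other named genes in basophils, nor for Nupr1 and Mt2 in stem cells, since its own filter removed them. No paired analysis was possible because the groups share no replicate numbers. Power was lower in the stem class than over all cells. A 2-fold change was recovered in 58.2% of simulated genes in stem cells and in 100% over all cells. In stem cells a 1.5-fold change was recovered in 16.4%.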

Other observations

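All tests of other splits and of lists within classes in this part were chosen after the results were seen.

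Within single classes, W41 libraries differed from WT in stress and signalling genes. Immediate early genes fell in erythroid cells (11 of 13 measured; adjusted over the list alone, 12; adjusted p = 6.12e-06, and adjusted p = 0.625 with an estimated correlation) and in the megakaryocyte lineage (9 of 14; adjusted over the list alone, 9; 0.000260, and adjusted p = 0.207 with an estimated correlation). They also fell in lymphoid cells (6 of 13; adjusted over the list alone, 6; 0.00660, and adjusted p = 0.570 with an estimated correlation). ERK feedback genes fell in erythroid cells, 9 of 11, with 1 higher (adjusted over the list alone, 9 and 1; 0.000703, and adjusted p = 0.463 with an estimated correlation). Erythroid cells were mostly of clusters 5, 8 and 9 in WT and of cluster 8 in W41, so both erythroid list changes hold a change of stage.

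Stem cells of W41 had more STAT5 target expression, in 4 of 7 genes (adjusted over the list alone, 4; 0.00611, and adjusted p = 0.479 with an estimated correlation), with Socs2 at 2.74. S phase genes fell in the same cells, 9 of 21 (adjusted over the list alone, 9; 0.00805, and adjusted p = 0.479 with an estimated correlation). Heat shock genes rose in stem cells, 5 of 8 (adjusted over the list alone, 5; 9.35e-06, and adjusted p = 0.479 with an estimated correlation), and in lymphoid cells, 5 of 8 (adjusted over the list alone, 5; 2.45e-06, and adjusted p = 0.570 with an estimated correlation). Lists within classes were tested under TMM alone. Over all cells, the library total changed STAT5 targets from 6 higher and 3 lower to 2 and 5. It changed heat shock genes from 8 higher and 2 lower to 4 and 4. The counts of genes that rose within a class may likewise depend on scaling. Whether these list changes differ between classes was not tested. Across genes, which are not independent replicates, Pearson's r between the W41 effects of a pair of classes ran from 0.551 (basophil and erythroid) to 0.826 (megakaryocyte and neutrophil).

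The 6 WT libraries can be split into groups of 3 in 10 ways, so a share under 0.1 cannot be reached. Each split other than the real one mixes LSK and LK libraries in both groups. The difference between LSK and LK then adds to the spread within groups, which holds down gene and class calls. Part of that difference also stays between the groups, so these splits give no level of calls by chance. For genes, 1 of the 10 splits, the real one, called as many as 11417 with edgeR, and the highest other called 0 (at most 62 at an unadjusted p under 0.05). For classes 1 of the 10 splits called as many as 8, and the highest other called 0, also at an unadjusted p under 0.05. For lists at the preset correlation 5 of the 10 splits called as many as 14, and the highest other called 17.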
